A study of Caenorhabditis elegans with 4 samples.

How the data were processed

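Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map PQN-85 in mixed-stage embryos of the wild-type Caenorhabditis elegans strain N2. PQN-85 is the worm counterpart of Scc2/NIPBL, the protein that loads cohesin onto chromosomes. Per the labels' protocols, embryos were collected by bleaching adults grown in liquid culture, fixed in 2% formaldehyde for 30 minutes, sonicated, and immunoprecipitated with an affinity-purified rabbit polyclonal antibody raised against part of PQN-85. The series held 4 samples: 2 ChIP samples, numbered replicates 1 and 2, and 2 input DNA samples. Whether the ChIP replicates came from separate cultures is not stated in the labels.

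The deposited data used here were 3 peak lists, 1 for each ChIP replicate and 1 for the whole series. No peak list or signal of the input samples was used here. Reads were aligned with BWA and ce10 was the build, per the submitters' processing notes, and coordinates are on WormBase WS220, per the file headers. Peaks of the replicates were called with MACS (no version given) and those of the series-level list with MACS v2, per the files' source columns. The caller's settings, the use of the inputs, any filter and the way the replicates entered the series-level list are not given in the sources used here. Each peak carries a start, an end and a score, and the deposited score is the authors' own value from the peak caller, with no normalization between lists. No header says which quantity the score is. The scores ran from 50.06 to 3194.52 in replicate 1, from 50.01 to 3171.85 in replicate 2 and from 1.36 to 109.24 in the series-level list. In replicates 1 and 2, 19 and 4 peaks were tied at exactly 3100. Scores were therefore used to rank peaks within a list, and across lists only in the planned correlation between the replicates, by ranks (Spearman) and by log10 scores (Pearson). Sequencing depth is unknown from peak lists, and no peak carries an error of its own.

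Analyses were done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The 6 nuclear chromosomes entered the comparisons, and mitochondrial peaks are described in the closing section. Chromosome lengths were taken as the largest coordinate listed for each chromosome (100.3 Mb in total), since no genome of the build was used here. Peaks of 2 lists counted as shared when they had at least 1 bp in common. The overlap expected by chance came from 10000 circular shifts of one list, each chromosome by its own random offset, which keeps peak widths and spacing. Numbers of peaks per chromosome were compared with chromosome length by exact binomial tests, with Benjamini-Hochberg adjustment over 6 chromosomes. The share of autosomal peak midpoints in the middle 33.3% of each chromosome was tested in the same way, without adjustment. The X shares of the replicates were compared by Fisher's exact test, median widths by 100000 permutations, and distances between neighbouring peaks with 1000 random placements. All tests were two-sided with a threshold of 0.05. Intervals are exact (Clopper-Pearson) 95% binomial intervals that treat peaks as independent. They cover counting error over peaks, not variation between embryo cultures.

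The tests, the alternatives and the rule for the regions named were fixed before the data were examined. Other comparisons are said to be added where they appear. The named regions are the 10 highest-scoring series-level peaks present in both replicate lists, the 3 highest-scoring peaks found in only one replicate (for each replicate) and the 3 windows of 100 kb with the most series-level peaks. Alternatives were a reciprocal overlap of 50%, midpoints within 200 bp, the higher-scoring 50% of a list, replicate lists of equal length, merging of peaks within 500 bp, base pairs covered in place of peak numbers, and each replicate list alone. Assignment of peaks to promoters, exons, introns and 22 gene lists had been planned and was not run, because the gene table used here is on WBcel235, another build. That table gave only the number of genes per chromosome.

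The statistics were tested on simulated data with the numbers of the real peaks. For the overlap and the distance, peaks of the real widths were placed at random on their chromosomes. For the X share, a chromosome was drawn for each peak independently, without widths or positions. No simulated list was clustered as the real peaks are, so error rates for clustered lists are not known. For the replicate overlap (676 peaks against the longer list), 3 of 100 pairs of unrelated lists passed the threshold. With 200 shared peaks placed in the lists, the mean excess over chance was 194.9. For the X share of 1006 series-level peaks, 5 of 100 lists placed by length passed, as did 100 of 100 lists in which X peaks were made 1.4 times as likely. These X calls used p-values without adjustment, unlike the test of the real lists. The seeded excess was also larger than the observed series-level ratio of 1.16, so the power at that ratio is not known. For the distance between peaks, 1 of 20 randomly placed lists of 676 peaks passed.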

Results

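The PQN-85 peaks of mixed-stage N2 embryos were narrow sites that covered about 1% or less of the nuclear genome in each list. The replicate 1 list held 1787 nuclear peaks over 966.3 kb (0.96% of the sequence) and the replicate 2 list held 676 over 512 kb (0.51%). The series-level list held 1006 nuclear peaks over 501.1 kb (0.50%). The median width was 388 bp in replicate 1 (interquartile range 226 to 581), 442.5 bp in replicate 2 (251 to 761.5) and 271 bp in the series-level list (188 to 473.75). The widest peak of every list lay near the right end of chromosome I and measured 11115 bp in replicate 1, 11099 bp in replicate 2 and 11157 bp in the series-level list. With 2 ChIP replicates and no peak list of the inputs, each property was compared between the 2 replicate lists and against chance placement.

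The first comparison asked whether the replicates found PQN-85 at the same sites. Of the 676 peaks of replicate 2, 574 overlapped a replicate 1 peak (84.9%, 95% interval 82.0 to 87.5). Of the 1787 peaks of replicate 1, 577 overlapped a replicate 2 peak (32.3%, 30.1 to 34.5). Circular shifts gave a mean of 14.5 shared replicate 2 peaks and at most 88, so the observed number was 39.6 times the mean by chance (permutation p = 0.0002, the smallest the 10000 shifts can give). When both lists were held to their 676 highest-scoring peaks, 64.6% of replicate 2 and 61.7% of replicate 1 peaks were shared.

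Sharing followed the peak score in both lists. In the highest-scoring 20% of replicate 1, 81.0% of 357 peaks were found in replicate 2 (76.5 to 84.9), against 9.24% of 357 in the lowest-scoring 20% (6.45 to 12.7). In replicate 2, the share fell from 98.5% of 135 peaks in the highest-scoring 20% (94.8 to 99.8) to 68.9% of 135 in the lowest (60.4 to 76.6). Shared peaks were also wider. Their median width was 600 bp against 320 bp for unshared peaks in replicate 1, and 500.5 bp against 224.5 bp in replicate 2 (permutation p = 1e-05 in each list, the smallest 100000 permutations can give). Across 462 peaks paired 1 to 1, the scores of the replicates had a Spearman's rho of 0.56 and their log10 values a Pearson's r of 0.61 (permutation p = 1e-05 for both). These correlations are across peaks, which are not independent replicates.

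**Figure D1:**
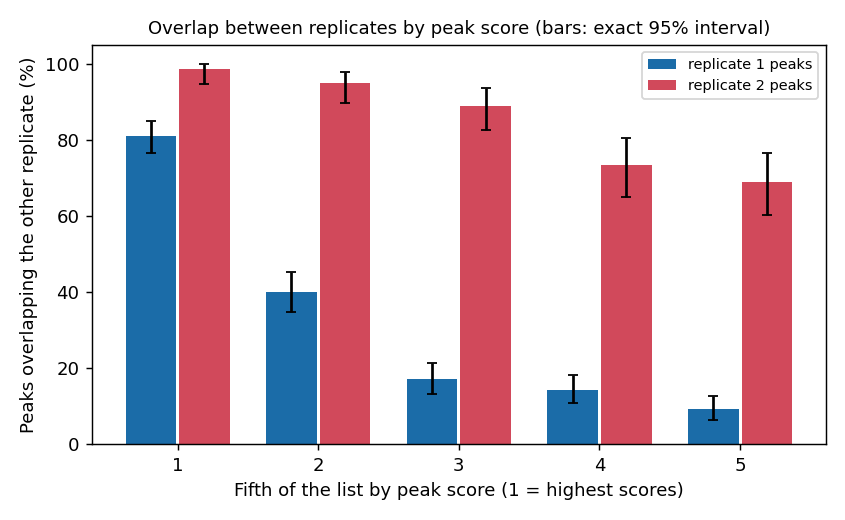
Percentage of peaks that overlap a peak of the other replicate by at least 1 bp, for 5 classes of equal size by peak score in the replicate 1 list (blue) and the replicate 2 list (red), with exact 95% binomial intervals. The share in replicate 1 drops from 81.0% in the highest class to 9.24% in the lowest, and in replicate 2 from 98.5% to 68.9%.

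The strongest sites found in all lists lay on chromosomes I, III, IV, V and X. The highest series-level score (109.24) belonged to a 1050 bp peak on X from 11605479 to 11606528 (WS220), with scores of 3006.07 in replicate 1 and 2115.73 in replicate 2. The next was the 11157 bp region on I from 15060228 to 15071384 (67.74), scored 3100 in both replicates. The ribosomal RNA gene array of this species lies at the right end of chromosome I. The left end of chromosome I, from base 1 to 474, ranked next with 64.19, and scored 1073.71 and 437.49 in replicates 1 and 2. Chromosome III held 2 of the 10 sites, from 10224496 to 10225518 (59.46) and from 3867335 to 3867687 (57.71), and IV held 1, from 14033597 to 14034637 (57.1). On X, a second site ran from 15807481 to 15811183 (59.07). Chromosome V held 3, from 5283172 to 5285888 (58.52), 17128145 to 17132123 (54.68) and 17119900 to 17126616 (53.14). The last 2 of these measured 3979 and 6717 bp. Genes at these sites were not analysed here, as no annotation on WS220 was used. Input signal at these sites was not compared here either, so a high score alone does not show strong PQN-85 binding.

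The strongest sites found in only 1 replicate lay on different chromosomes in each. The 3 highest-scoring replicate 1 peaks without a replicate 2 peak were all on X, from 2996711 to 2997441 (score 1924.33), 12362791 to 12363510 (1727.85) and 14525571 to 14526151 (1466.94), and measured 581 to 731 bp. The 3 highest replicate 2 peaks without a replicate 1 peak were all on III. A pair of adjoining peaks ran from 2077591 to 2080312 (754) and from 2080318 to 2082646 (560.13), and the other from 13447303 to 13447771 (354.84).

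The second comparison asked how the series-level list relates to the replicates. Of its 1006 nuclear peaks, 568 overlapped peaks in both replicates (56.5%, 53.3 to 59.6), 202 in replicate 1 alone (20.1%, 17.6 to 22.7), 62 in replicate 2 alone (6.16%, 4.76 to 7.83) and 174 in neither (17.3%, 15.0 to 19.8). The peaks found in both replicates had a median width of 380 bp and a median score of 10.8, against 186 bp and 4.68 for those found in neither. In the other direction, the series-level list held 528 of the 577 replicate 1 peaks shared with replicate 2 (91.5%) and 197 of the 1210 unshared ones (16.3%). It held 67 of the 102 replicate 2 peaks that replicate 1 lacked (65.7%). The list was therefore neither the union nor the intersection of the replicate lists. With a reciprocal overlap of 50%, 28.4% of the series-level peaks were found in both replicates and 48.0% in neither.

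The third comparison set the number of peaks on each chromosome against its length, with X as the lead because the hermaphrodite X is bound by the condensin-like dosage compensation complex. Chromosome V carried fewer peaks than its length gives, and X carried more in replicate 1. In the series-level list V held 154 peaks where 210 were expected (ratio 0.73, 0.63 to 0.85, exact binomial adjusted p = 4.7e-05). The V ratio was 0.71 in replicate 1 (0.63 to 0.79, exact binomial adjusted p = 2.1e-10) and 0.84 in replicate 2 (0.71 to 0.99, exact binomial adjusted p = 0.11), so the deficit passed the test in replicate 1 and did not in replicate 2. By base pairs covered, V held 20.6% of the series-level total, 17.8% of the replicate 1 total and 21.8% of the replicate 2 total, against 20.9% of the length.

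X held 207 of 1006 series-level peaks (20.6%) against 17.7% of the length, a ratio of 1.16 (1.03 to 1.31) that missed the threshold after adjustment (exact binomial p = 0.018, adjusted p = 0.055). The ratio was 1.26 in replicate 1 (397 of 1787 peaks, 1.15 to 1.37, exact binomial adjusted p = 3.2e-06) and 1.14 in replicate 2 (136 of 676, 0.97 to 1.32, exact binomial adjusted p = 0.19). The difference between the X shares of the replicates, 22.2% and 20.1%, did not pass the test (Fisher's exact p = 0.27). That test treats the lists as independent, though 574 of the 676 replicate 2 peaks overlapped a replicate 1 peak. It therefore does not show that the X shares are alike. Chromosome III was above expectation in replicate 1 (ratio 1.14, exact binomial adjusted p = 0.047), and its ratios were 1.25 in replicate 2 (adjusted p = 0.071) and 1.08 in the series-level list (adjusted p = 0.44). Chromosomes I, II and IV passed the adjusted test in none of the 3 lists. In the series-level list the ratio of I was 1.15, close to that of X (exact binomial p = 0.047, adjusted p = 0.094). Among series-level peaks found in both replicates, I and X each had a ratio of 1.19. Shares over chromosomes add up to the whole, so the V deficit raises the ratios of the others. That part was not taken out of the X ratio.

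**Figure D2:**
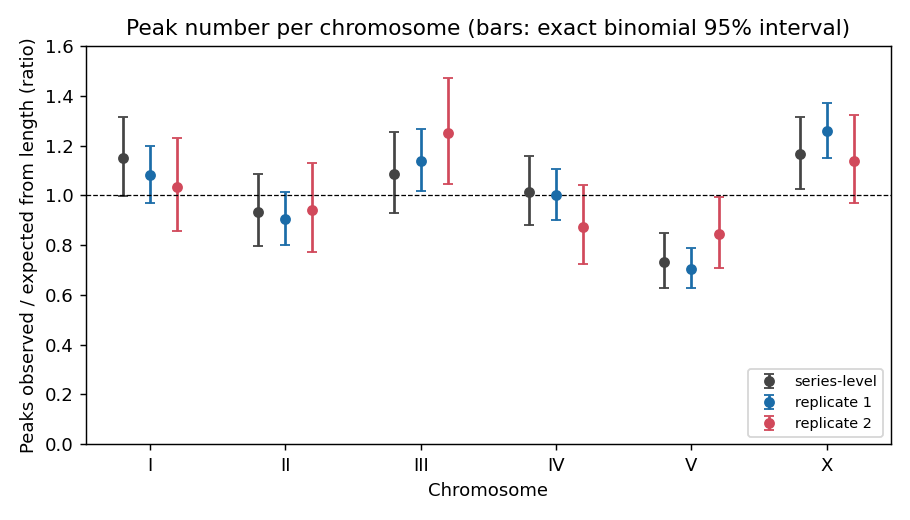
Number of peaks on each chromosome divided by the number expected from its length (ratio), for the series-level list (grey) and the replicate lists (blue and red), with exact 95% binomial intervals. The V ratios lie at 0.73, 0.71 and 0.84 and the X ratios at 1.16, 1.26 and 1.14.

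The fourth comparison set autosome centres, which are gene dense in this organism, against the arms. In the series-level list 302 of 799 autosomal peaks had their midpoint in the middle 33.3% of the chromosome (37.8%, 34.4 to 41.3, exact binomial p = 0.0086). The share was 40.8% in replicate 1 (38.2 to 43.4, exact binomial p = 7.1e-09) and 35% in replicate 2 (31.0 to 39.2, exact binomial p = 0.41). In the series-level list the share was 44.4% on IV (37.0 to 52.0) and 41.6% on V (33.7 to 49.8), and 33.3% on I, 36.4% on II and 32.7% on III. The replicates did not share this order: replicate 1 had 45.6% on V, 42.7% on II, 40.5% on III, 39.4% on IV and 36.6% on I, and replicate 2 had 40.2% on II, 35.9% on IV, 35.3% on III, 33.6% on V and 30.5% on I. On X it was 30.4% in the series-level list (24.2 to 37.2), 28.5% in replicate 1 (24.1 to 33.2) and 24.3% in replicate 2 (17.3 to 32.4). The exact binomial p for X was 0.42, 0.043 and 0.029 in that order, without adjustment. X thus lay below 33.3% in both replicates, though X was outside the planned autosomal test and the replicate lists share peaks. The higher share in autosome centres did not pass the test in replicate 2, nor among series-level peaks found in both replicates (36.7%, exact binomial p = 0.13).

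Peaks lay closer together than random placement gives. The median distance between the midpoints of neighbouring series-level peaks was 45.0 kb, against a mean of 67.8 kb over random placements (permutation p = 0.002, the smallest 1000 placements can give). The medians were 28.1 kb in replicate 1, against 37.9 kb at random, and 68.7 kb in replicate 2, against 101 kb (permutation p = 0.002 each). Of 1005 windows of 100 kb, 500 held no series-level peak and 34 held 5 or more. The densest window, on I from 10200001 to 10300000, held 21 series-level, 16 replicate 1 and 9 replicate 2 peaks, where the means per window were 1.00, 1.78 and 0.67. Next were a window on V from 8800001 to 8900000, with 13, 11 and 7 peaks, and one on II from 13800001 to 13900000, with 10, 9 and 6. After peaks within 500 bp were merged, the median distance was 72.7 kb against 82.5 kb at random (permutation p = 0.002).

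**Figure D3:**
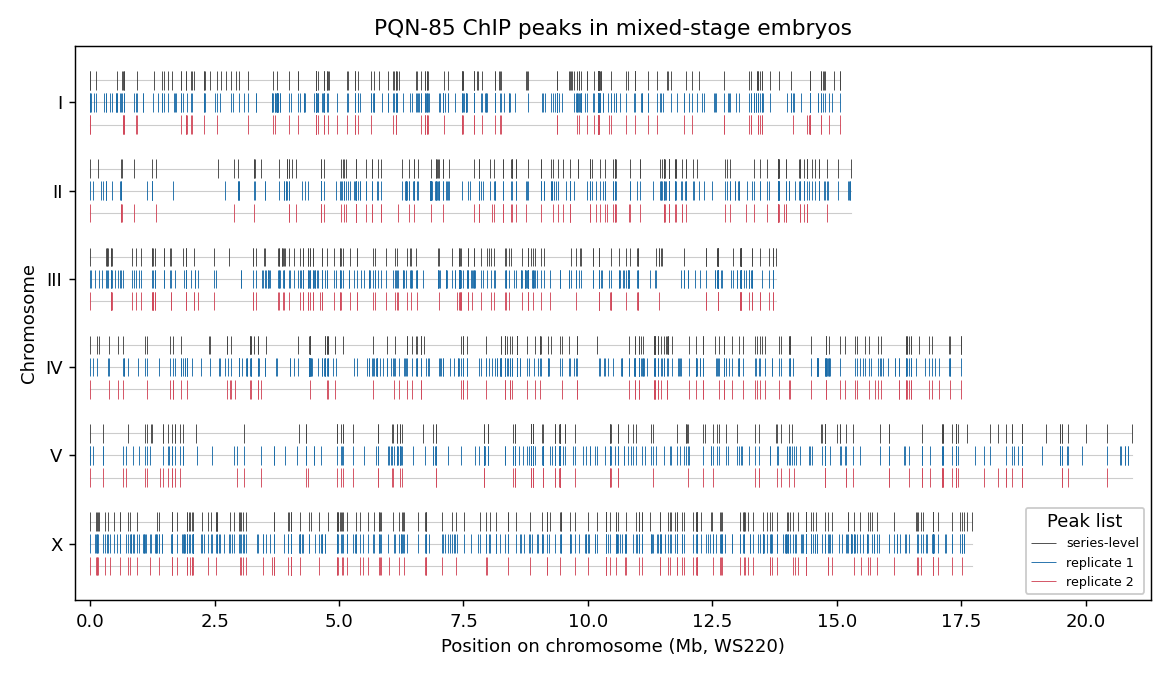
Positions of the peak midpoints (Mb, WS220) on the 6 nuclear chromosomes, 1 tick per peak, for the series-level list (grey), replicate 1 (blue) and replicate 2 (red). The 1787 replicate 1 peaks are spread over all chromosomes, and V, the longest, carries 154 of the 1006 series-level peaks.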

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

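The tests of the chromosome of the strongest unshared peaks were chosen after those peaks were seen, and the test for a small shift in position was written before its result. The series-level list held 9 peaks on mitochondrial DNA, which no comparison above used and for which no input list was used here. They scored 4.35 to 30.67, with a median of 19.1 against 6.96 for nuclear peaks, and covered 78.2% of the sequence up to the last listed base. Replicate 1 held 2 mitochondrial peaks, which covered 99.5%, and replicate 2 held 0.

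The replicate 1 list held more peaks than the replicate 2 list (1787 against 676). Splitting of the same regions is argued against, since after merging within 5000 bp the lists still held 1290 and 470 regions, a ratio of 2.74. Lower sensitivity in replicate 2 at the same sites predicts that few of its strong peaks lack a replicate 1 peak. In the higher-scoring 50% of replicate 2, 4.73% lacked one (16 of 338, 2.73 to 7.57). This value does not bear on the replicate 1 peaks that replicate 2 lacks. It therefore cannot decide whether those are further binding sites. Sequencing depth of the replicates was not analysed here, and no biological explanation was tested.

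A part of replicate 1 may depart from the account of lower sensitivity in replicate 2. Of the 10 strongest replicate 1 peaks missing from replicate 2, 8 lay on X, with scores from 967.55 to 1924.33 over the 10. Among the highest-scoring 20% of replicate 1 peaks, X held 30 of the 68 missing ones (44.1%, 32.1 to 56.7) and 65 of the 289 shared ones (22.5%, 17.8 to 27.7, Fisher's exact adjusted p = 0.0033 over 5 score classes). Without the 3 named peaks that prompted the test the odds ratio was 2.45 (Fisher's exact p = 0.0027, without adjustment). The other X peaks among the 10 strongest stayed in that test. Lower sensitivity alike on all chromosomes predicts like X shares only if X and autosomal peaks are alike in score and width. Missing and shared peaks were not matched by either, so the value cannot decide against it. The test was also chosen after peaks were seen. In the 4 lower classes the odds ratios were 1.79, 1.31, 1.13 and 1.35 and did not pass (Fisher's exact adjusted p from 0.097 to 0.85). A small shift in position is argued against, as 0% of the 30 missing X peaks, which were 484 to 964 bp wide, had a replicate 2 peak within 500 bp. The series-level list held 13 of these 30 peaks and lacked 17. An untested hypothesis is that these peaks may include X sites of the dosage compensation complex, through association with PQN-85 or through DNA of another library, and no list of such sites was used here.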

How the results depend on the processing

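Of 51 alternative values, 33 kept their direction and their side of the threshold, or moved by less than their interval, and 0 reversed. Kept throughout were the replicate overlap (replicate 2 peaks shared 63.2% to 87.9%, replicate 1 peaks 23.9% to 61.7%, permutation p = 0.0002 in each), the score correlation, the wider shared peaks, the clustering and the unpassed test of the replicates' X shares. Alternatives added after the data were seen were merging within 5000 bp, gene numbers as expectation, chromosome ends left out, a tolerance of 500 bp, and the peaks found in both replicates. The X ratio passed the adjusted test with peaks within 500 bp merged (1.19, exact binomial adjusted p = 0.041), within 5000 bp merged (1.26), against protein-coding gene numbers (1.51) and with chromosome ends left out (1.17, exact binomial adjusted p = 0.042). It did not pass in the higher-scoring 50% of the list (1.11, exact binomial adjusted p = 0.69) or among peaks found in both replicates (1.19, exact binomial adjusted p = 0.11), and was 1.09 by base pairs covered, which has no test. The ratio against gene numbers had to exceed the ratio to length, as X holds a smaller share of those genes than of the length. Over all X alternatives with a test, the exact binomial adjusted p ran from 6.0e-09 (gene numbers) to 0.69. By single replicate the X ratio ran from 1.14 to 1.26 and the V ratio from 0.71 to 0.84, and the replicate 2 list alone passed for neither. The V ratio missed the threshold in the higher-scoring 50% of the list (0.77, exact binomial adjusted p = 0.0501) and was 0.99 by base pairs covered, because V peaks held more base pairs each. The autosome-centre share lost its call in the higher-scoring 50% (37.4%) and among peaks found in both replicates (36.7%), and ran from 35% to 40.8% by single replicate. The cause was not tested. With 50% reciprocal overlap, series-level peaks were found in both replicates for 28.4%, replicate 1 alone for 10.1%, replicate 2 alone for 13.4% and neither for 48.0%. In the higher-scoring 50% the shares were 79.1% in both, 8.55% in replicate 1 alone and 7.55% in neither. No paired analysis was possible because the inputs, which share the replicate numbers, had no list here. The planned gene feature and gene list comparisons were not run for want of an annotation on the same build. Peak lists carry no depth, so a missing peak was not called at the authors' threshold and is not shown to be unbound.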

Other observations

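The tests on peaks of 2 kb or wider, chromosome ends and X peak widths were chosen after the data were seen. The X ratio of each replicate was a planned value, and its use to weigh whether 1 replicate gives the excess was written after it was seen. Peaks 2 kb or wider were found repeatedly. Replicate 2 held 49 of them, of which 47 overlapped a replicate 1 peak (95.9%, 86.02 to 99.50), against 84.1% of its narrower peaks (80.9 to 86.8), so these intervals overlap. Replicate 1 held 52, of which 44 overlapped a replicate 2 peak (84.6%, 71.9 to 93.1), against 30.7% of its narrower peaks (28.6 to 33.0). In the series-level list 36 of 38 such peaks were present in both replicates (94.7%, 82.3 to 99.4), against 55.0% of the narrower peaks (51.8 to 58.1), and the wide peaks made up 27.6% of the covered base pairs. X held 7 of these 38 (18.4%, 7.74 to 34.3) against 17.7% of the length. Shared replicate 1 peaks also had higher scores than unshared ones (median 324.58 against 91.085). Wide peaks were not compared with narrower peaks of like score, so the part of width alone is not known.

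Every chromosome began with a peak, though input signal at these ends was not compared here. In each of the 3 lists a peak lay within 100 bp of base 1 on 6 of 6 chromosomes, with scores of 10.88 to 64.19 in the series-level list (median of the whole list 6.96), 230.23 to 1073.71 in replicate 1 (median 126) and 79.35 to 437.49 in replicate 2 (median 138). Within 100 bp of the largest listed coordinate, the series-level list held a peak on 6 of 6 chromosomes and the replicate lists on 0 of 6. Since chromosome lengths were taken from the largest coordinates in the lists, and the replicate lists hold none there, the count for the series-level list is fixed by that definition and is not a finding. In replicate 1, X peaks had a median width of 440 bp against 371.5 bp on autosomes (permutation adjusted p = 0.0041 over 6 comparisons). The medians were 426.5 and 446.5 bp in replicate 2 (permutation adjusted p = 0.70) and 261 and 274 bp in the series-level list (adjusted p = 0.67).

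The X ratio over length was examined for causes. Finer splitting of X peaks is argued against, since the ratio was 1.26 (1.09 to 1.45, exact binomial p = 0.0016) after merging within 5000 bp. X peaks were 1.51 times (1.33 to 1.70) the X share of protein-coding genes. X holds 13.7% of those genes against 17.7% of the length, so peaks that followed gene numbers would give no X excess over length. The ratio to gene share therefore had to exceed the ratio to length, and it adds no separate evidence for the excess. Whether the excess comes from replicate 1 alone stays open, as the replicate 2 ratio was 1.14 with an interval of 0.97 to 1.32. The part of the X ratio that follows from the V deficit was not taken out. No biological explanation was tested, and the inputs' X coverage was not analysed here.

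A hypothesis was that chromosomes with more tRNA genes hold more peaks per Mb. Across the 6 chromosomes, Spearman's rho was 0.94 for the series-level list (exact permutation p = 0.017, adjusted p = 0.05 over 6 relations) and Pearson's r was 0.51 (exact permutation p = 0.17). In the replicates Pearson's r was 0.67 (exact permutation p = 0.17) and 0.45 (exact permutation p = 0.39). The replicates' rank correlations with tRNA genes are not given here, so these values alone do not show that the relation fails in them. Without V and X, the chromosomes farthest from the median tRNA density, Pearson's r was 0.84 in the series-level list, 0.997 in replicate 1 and 0.83 in replicate 2 over 4 chromosomes, too few to test the relation. V and X were left out together, so the rise is not assigned to either. X stands apart at 15.6 tRNA genes per Mb against 3.73 to 4.64 on the autosomes, while its 11.7 peaks per Mb are close to the 11.5 of chromosome I. With protein-coding genes per Mb, rho was -0.83 in the series-level list (exact permutation p = 0.058) and Pearson's r was -0.89 (exact permutation p = 0.025, without adjustment). In replicate 1 these were -0.77 (exact permutation p = 0.10) and -0.94 (exact permutation p = 0.011), and in replicate 2 -0.43 (exact permutation p = 0.42) and -0.61 (exact permutation p = 0.19). Without V and X, Pearson's r with protein-coding genes was weaker, at -0.75 in the series-level list, -0.78 in replicate 1 and -0.25 in replicate 2. These values also rest on 4 chromosomes. Both relations rest on 6 chromosomes and may be due to other differences between them, and no test by position was possible without coordinates on the same build.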
